A study of Homo sapiens with 4 samples.

How the data were processed

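Total RNA of 4 human bladder urothelial carcinoma samples was measured, the lines 5637 and T24 and their platinum-resistant sublines 5637PR and T24PR, with 1 array per sample. Per the labels' protocols, RNA was isolated with a phenol-based reagent and a column kit, and biotin-labelled with a whole-transcript kit for Affymetrix arrays. The values are log2 expression summaries per probe set, as deposited by the authors. Their scale was read from the values, which lay above 4 on every array with no centring of genes. The method of summarisation, background correction and normalization between arrays is not given in the sources used here, and no scanner file was used here. The values carry no detection calls, so whether a gene near the lowest array value was above background is not known.

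Groups were taken from the labels: parental (5637, T24) and platinum-resistant (5637PR, T24PR), 2 arrays each. The pairing comes from the labels, which say which line each subline was established from, and each subline correlated best with its own line. Nothing in the labels says that arrays stand for repeated cultures, so p-values of single genes measure the spread between the 2 lines' differences on these arrays. All columns of the table were used, and 0 columns of other samples were present.

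Of 28869 probe sets, 19310 carried 1 gene symbol in the platform annotation, 1752 several and 7807 none. Probe sets with 1 symbol were renamed through their Entrez ID with the RefSeq gene table of GRCh38.p14, where 19279 matched and 31 kept their file name. The build of the array annotation is not named, so this table served only for names, RNA classes, gene spans and the order of neighbouring genes, and no coordinates are given. The result was 18377 genes, of which 685 had more than 1 probe set and were represented by the probe set with the highest mean over the 4 arrays. A gene was kept when the highest of its 4 values reached the median of all named values (log2 5.68), which left 10956 genes.

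For each line the log2 difference of the resistant minus the parental array was computed per gene, with counts at 2-fold or more and no p-value. The overlap of both lines was compared with the product of the 2 counts over the number of genes, per direction. The shared change was fitted in limma 3.58.1 under R 4.3.3 with lmFit on cell line and resistance and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method at 0.05, two-sided. The fit had 1 residual degree of freedom and a prior of 4.76, and the median moderated standard deviation was 0.31. The 35 gene lists held 1062 distinct genes, of which 944 were measured and 752 kept. Each list's median was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. Over both lines the lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 35 lists. Camera compares a list with the other genes, while fry tests whether its genes move one way on balance. At the preset correlation the p of camera rests on the spread over genes, and not on the spread between the 2 lines.

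The lists were interferon-stimulated genes, NF-kB and inflammatory cytokines, ubiquitin ligases acting on EMT factors or in muscle atrophy, proliferation, unfolded protein and ATF4 response, epithelial, mesenchymal, EMT transcription factors, luminal, basal, platinum transport, metallothioneins, NRF2 and glutathione, nucleotide excision repair, crosslink repair, mismatch repair, p53 targets, apoptosis, angiotensin and angiogenesis, antigen presentation, TGF-beta, YAP targets, WNT, hypoxia and glycolysis, sterol synthesis, stem cell markers, receptor tyrosine kinases, ERK feedback, cancer testis antigens, ribosomal proteins, oxidative phosphorylation, housekeeping genes, and leukocyte, endothelial and fibroblast markers. The ubiquitin list also holds deubiquitinases.

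The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per line, the 10 genes with the largest difference in each direction whose higher value reached the filter threshold. It further names the 10 genes in each direction with the largest smaller difference among those 2-fold in both lines, up to 5 genes in each opposite direction, and the 5 largest differences of the parental lines in each direction. For each list and line up to 4 members with the largest difference may be named, and FBXO32, CDH1, CDH2, VIM, SNAI1, ZEB1, AGTR1, SLC31A1, ATP7A, ATP7B, ABCC2 and ERCC1 always are. HSPA5 and CLDN7 in the text and EPCAM, GAMT, ODC1 and PLIN2 in the plots fall outside this rule and were chosen after their values were seen.

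The limma script was tested on simulated values for the 10956 genes before use. It called 16 of 67 genes with a simulated log2 change of 2, 56 of 66 with a change of 3, 0 of 67 with a change of 1 and 6 of 10756 unchanged genes, and with no gene changed 5.47% of genes had an unadjusted p under 0.05. Alternatives were quantile normalization, cyclic loess, no filter, a filter on the mean of the 4 values, the mean of a gene's probe sets, no block on cell line, eBayes without a trend, an estimated correlation in camera, an overlap at 1.5-fold, and each line left out. Removing a loess trend of each pair's difference on gene span was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.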

Results

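Gene expression was measured in 5637 and T24, 2 human bladder urothelial carcinoma cell lines, and in 5637PR and T24PR, sublines derived from each of them that had acquired resistance to platinum drugs. The title of the series asks which molecules connect acquired platinum resistance with changes that resemble an epithelial-mesenchymal transition (EMT), the shift in which epithelial cells lose junction proteins and gain mesenchymal ones. Total RNA of each line was hybridised to 1 Affymetrix whole-transcript array, so the parental group and the resistant group held 2 arrays each and the 2 lines served as the replicates. Each single-line comparison rests on 1 array per side and has no replicate check, and the number of arrays limits the precision of every value below. Over the 28869 probe sets the lowest deposited log2 value lay between 4.13 and 4.16 on the 4 arrays, the median between 5.16 and 5.26, and the highest between 13.53 and 13.74. Genes near the lowest value have little room to be lower, and values under the filter threshold of 5.68 are not shown to be above background, so the size of a difference from such a value is uncertain. After naming and filtering, 10956 of 18377 named genes were compared. Across these genes the Pearson correlation, which describes arrays and does not treat genes as replicates, was 0.968 between 5637 and 5637PR and 0.877 between T24 and T24PR. Each subline was closer to its own parental line than to the other line, as 5637 and T24PR correlated at 0.803 and 5637PR and T24 at 0.703.

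The first comparison asked what differed in 5637PR from its parental line 5637. The interferon-induced gene IFI6 was 12.5-fold higher in 5637PR, at a log2 value of 10.10 against 6.46. PTGS2, which encodes the inducible cyclooxygenase, was 7.58-fold higher, and AKR1C2, an aldo-keto reductase gene, was 7.40-fold higher. The tetraspanin gene TSPAN1 was 6.04-fold higher and the interferon-induced membrane protein gene IFITM1 5.29-fold higher. In the other direction the amino acid transporter gene SLC38A5 was 10.8-fold lower, at 5.46 against 8.89, the cytidine deaminase gene APOBEC3B differed by -2.32 on the log2 scale, and FN1, which encodes fibronectin, was 3.42-fold lower. Of the genes compared, 91 were at least 2-fold higher and 136 at least 2-fold lower in 5637PR, together 2.07% of genes, and the standard deviation of the log2 differences was 0.38. Of the 136, 46 (33.8%) lay in 12 blocks of neighbouring genes, which held 4.03% of the genes with a known position. The blocks were picked after seeing the data for low medians in this same pair, a choice that itself raises this number. Among the 46 were SLC6A11, NETO1, SPARC, PLAGL1, GOSR1 and GTF3C6. A difference of 4-fold or more was seen in 7 genes that were higher and 4 that were lower. The further genes with the largest differences were EMC10 (log2 difference 2.28), SLC7A8 (2.09), OLR1 (1.94), ENTPD3 (1.88) and the tissue factor gene F3 (1.84) on the higher side. On the lower side they were CYGB (-2.15), SLC6A11 (-2.03), VGLL1 (-1.97), KLK10 (-1.90), LYPD1 (-1.87), NETO1 (-1.66) and IFITM10 (-1.65). The balance of directions moved with the scaling, since 40.1% of the 2-fold differences were toward higher values as deposited, 50.7% after quantile normalization and 56.6% after cyclic loess.

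Gene lists written before the data were examined were set against 10000 random lists of the same size and mean expression, as a description of the 2 arrays of a line. In 5637PR, interferon-stimulated genes stood highest, with a median log2 difference of 0.28 over 24 genes, at percentile 100 of the random lists. Of these 24 genes, 3 were 2-fold higher and 0 were 2-fold lower. They were IFI6, IFITM1 and IRF9 (1.40), and IFITM3 was higher by 0.97. Basal and squamous genes had a median of 0.24 over 23 genes (percentile 99.97), with the basal keratin gene KRT14 higher by 1.72 and GSDMC by 1.02, while the cornified envelope gene SPRR2A differed by -1.40. Angiotensin and angiogenesis genes had a median of 0.26 over 16 genes (percentile 99.8) with 0 genes past 2-fold in either direction, VEGFB at 0.76 and NRP1 at -0.98. YAP target genes had the lowest median, -0.32 over 23 genes (percentile 0.52), with AMOTL2 at -1.09, TGFB2 at -1.08 and CCN2 at -0.89, although F3 of the same list was higher. Stem cell markers had a median of -0.31 over 12 genes (percentile 0.96), with ALDH1A3 at -1.14 (-0.70 with the mean of its probe sets), KLF4 at -1.03 and CD24 at -0.97. EMT transcription factors had a median of -0.25 over 15 genes (percentile 0.99), with SOX9 at -1.29 and SOX4 at -1.17. The mesenchymal list (median -0.23, percentile 0.19), the proliferation list (median -0.20, percentile 2.27) and the unfolded protein and ATF4 list (median -0.18, percentile 2.32) also lay low. In all, 9 of 35 lists lay outside the range from percentile 2.5 to 97.5, where independent lists would give 1.75. Random lists do not reproduce any common variation of a list's genes, and some lists share genes, such as KLF4 in the luminal and stem cell lists. The 1.75 is therefore not a strict reference, and this excess was not tested.

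The second comparison asked the same of T24PR and T24. CGA, which encodes the alpha subunit of the glycoprotein hormones, was 34.1-fold higher in T24PR, at a log2 value of 12.01 against 6.92. IGSF10 was at 8.17 in T24PR and 4.45 in T24 and SUCNR1, the succinate receptor gene, at 7.11 and 4.25, the lower values being under the filter threshold. TXNIP, which encodes the thioredoxin-interacting protein, was 8.69-fold higher and the complement gene C3 8.37-fold higher. The cytokine gene IL32 was 6.12-fold higher, and PLAT (tissue plasminogen activator) was at 8.37 against 5.52. MAL2, a gene of apical transport in epithelial cells, was lower in T24PR, at 4.92 against 9.85. Of the enzymes of sterol synthesis, HMGCS1 was 8.18-fold lower and IDI1 7.88-fold lower. The proteasome gene PSMA4 was 8.20-fold lower and SERPINB5, which encodes maspin, 7.04-fold lower. At 2-fold or more, 642 genes were higher and 1318 lower in T24PR, 17.9% of the genes compared, and at 4-fold or more 37 were higher and 96 lower. The standard deviation of the log2 differences was 0.75, against 0.38 in the 5637 pair. Of the genes 2-fold lower in T24PR, 75.2% were also 2-fold lower in 5637 than in T24, against 19.6% of all genes compared. Of those 2-fold higher in T24PR, 22.1% were also 2-fold higher in 5637 than in T24, against 11.5%. Both comparisons share the T24 array, which itself raises these shares. Other genes with large differences were QPRT (log2 difference 2.61), MAP3K12 (2.47) and the small nucleolar RNA SNORA38B (2.34), and on the lower side SVOPL (-3.06), MAGED1 (-3.05), PTBP2 (-2.98), NPR3 (-2.82) and RIMOC1 (-2.81). The T24 array stood apart, by a count chosen after seeing the data: in 813 genes, 712 of them higher in T24, it lay at least 1 on the log2 scale from the mean of the other 3 arrays while those lay within 0.5 of each other, against 161 such genes for T24PR, 31 for 5637 and 23 for 5637PR. With the trend on gene span removed, an alternative added after seeing the data, 46.4% of the 2-fold differences were toward higher values in T24PR, against 32.8% as deposited, 39.6% after quantile normalization and 27.1% after cyclic loess.

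In T24PR the list of ubiquitin ligases acting on EMT factors or in muscle atrophy had the lowest median, -0.73 over 24 genes, at percentile 0.02 of the random lists, with 0 genes 2-fold higher and 8 genes 2-fold lower. Among them were FBXO32 (-1.55), MDM2 (-1.76) and FBXO45 (-1.51), and PSMD14 (-1.78), which is a deubiquitinase of the proteasome and not a ligase. Genes of crosslink and homologous recombination repair had a median of -0.50 over 35 genes (percentile 0.21), with 1 gene 2-fold higher and 7 lower, among them NBN (-2.33), USP1 (-1.70), RAD51C (-1.32) and PALB2 (-1.29). Proliferation genes had a median of -0.33 over 45 genes (percentile 0.04), with 1 gene 2-fold higher and 8 lower, among them the mitotic kinase gene CDK1 (-2.55), CCNE2 (-2.34) and KIF11 (-1.78). Oxidative phosphorylation genes (median -0.17 over 34 genes, percentile 2.14, ATP5F1C -1.98) and unfolded protein and ATF4 genes (median -0.19 over 39 genes, percentile 2.28, NUPR1 -1.67) were the other low lists. The medians of 5637 minus T24 over the same lists were -0.23 for the ubiquitin ligases, -0.72 for crosslink repair, -0.59 for proliferation, -0.39 for oxidative phosphorylation and -0.42 for the unfolded protein list, so each of these lists was also lower in 5637 than in T24, in a comparison that shares the T24 array. Interferon-stimulated genes had a median of 0.32 over 24 genes (percentile 99.6). PSMB9 (1.37) and LGALS3BP (1.31) were higher, while IFIT2 (-1.70) and OASL (-1.66), both induced by interferon, were lower. Antigen presentation genes (median 0.51 over 9 genes, percentile 98.6, HLA-DMA 1.79), cancer testis antigens (median 0.48 over 7 genes, percentile 98.04, MAGEA1 2.15) and genes of the negative feedback of ERK signalling (median 0.38 over 24 genes, percentile 99.2, ETV4 1.51) were the other high lists. Here too 9 of the 35 lists lay outside percentiles 2.5 to 97.5, with the same limits as in the 5637 pair.

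**Figure D1:**
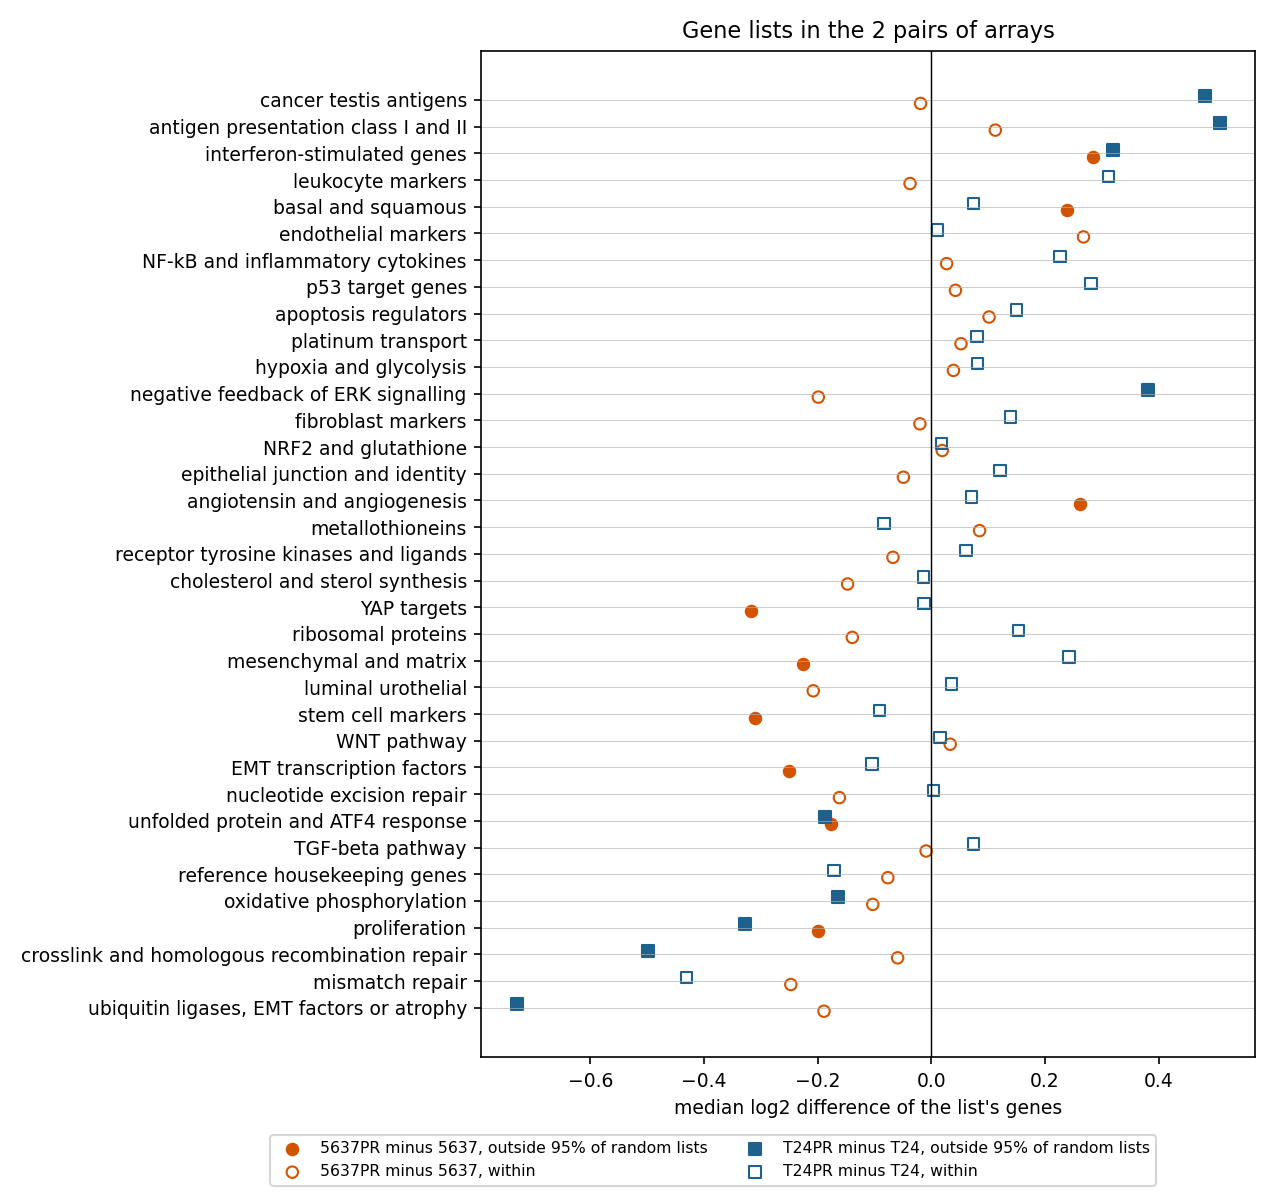
Median log2 difference (x axis) of each of the 35 gene lists (y axis) in 5637PR minus 5637 (circles) and T24PR minus T24 (squares), 1 array per side, with filled symbols for medians outside percentiles 2.5 to 97.5 of 10000 random lists. Interferon-stimulated genes lie high in both pairs (0.28 and 0.32), and proliferation genes lie low in both (-0.20 and -0.33).

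The third comparison asked which genes differed the same way in both resistant sublines. TSPAN1 was higher in 5637PR and T24PR by 2.59 and 2.15 on the log2 scale, and the amino acid transporter gene SLC38A5 differed by -3.43 and -2.71. The adhesion molecule gene ICAM1 was higher by 1.74 and 1.44 and the bradykinin receptor gene BDKRB1 by 1.46 and 2.14. FBXO32, which encodes an F-box subunit of a ubiquitin ligase, was lower in both sublines, with differences of -1.45 and -1.55. The FBXO32 value in T24PR (4.82) was under the filter threshold, so the size of the second difference is uncertain. In limma with the cell line as a block, 0 genes passed an adjusted p of 0.05 (the smallest was 0.683), and 613 genes had an unadjusted p under 0.05, 236 higher and 377 lower in the resistant sublines, close to the 599 genes in simulated data with no gene changed. For SLC38A5 the fit gave a log2 difference of -3.07 with a standard error of 0.31, for TSPAN1 2.37 with 0.31, for BDKRB1 1.80 with 0.30 and for FBXO32 -1.50 with 0.27, each with an adjusted p of 0.683. In simulated data with the same number of arrays and genes the fit called 0 of 67 genes changed by 1 on the log2 scale, 16 of 67 changed by 2 and 56 of 66 changed by 3, so most genes of the size of BDKRB1 or FBXO32 were out of its reach there. These shares depend on how many genes were changed at once and on the simulated spread. They do not carry over directly, as SLC38A5 at -3.07 was not called in the measured data. Without the block on cell line, 36 genes had an unadjusted p under 0.05 on the higher side and 32 on the lower side.

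By size alone, 20 genes were at least 2-fold higher in both sublines, where independent lists would give 5.33, and 22 were at least 2-fold lower in both, where they would give 16.4. After cyclic loess, 14 genes were 2-fold lower in both. The genes higher in both also held IFI6, IFITM1, the small Cajal body RNA SCARNA10 (1.41 and 1.85), the ephrin gene EFNA3 (1.38 and 1.42), the carnitine acetyltransferase gene CRAT (1.28 and 1.32), ABCA2 (1.27 and 1.26), STARD10 (1.25 and 1.38), SLC33A2 (1.19 and 1.20) and the noncoding gene MIR31HG (1.17 and 1.29). The genes lower in both also held LANCL2 (-1.28 and -1.39), HERPUD1 of the endoplasmic reticulum stress response (-1.17 and -1.29), PLAGL1 (-1.16 and -1.21, the latter -0.92 with the span trend removed), RBX1 (-1.16 and -1.76), GOSR1 (-1.15 and -1.26), the cold-induced RNA-binding protein gene RBM3 (-1.14 and -2.17), RPS7 (-1.14 and -1.61) and GTF3C6 (-1.13 and -1.15). RBX1 encodes the RING subunit of cullin ubiquitin ligases. Another 9 genes were past 2-fold in opposite directions, where independent lists would give 18.9, such as the protease inhibitor gene SLPI (1.65 in 5637PR and -2.05 in T24PR) and the creatine kinase gene CKB (-1.57 and 1.05). Across genes the log2 differences of the 2 pairs had a Pearson correlation of 0.204, a Spearman correlation of 0.233 and a covariance of 0.0588, and 59.7% of genes had the same sign in both. The 2 pairs share no array.

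**Figure D2:**
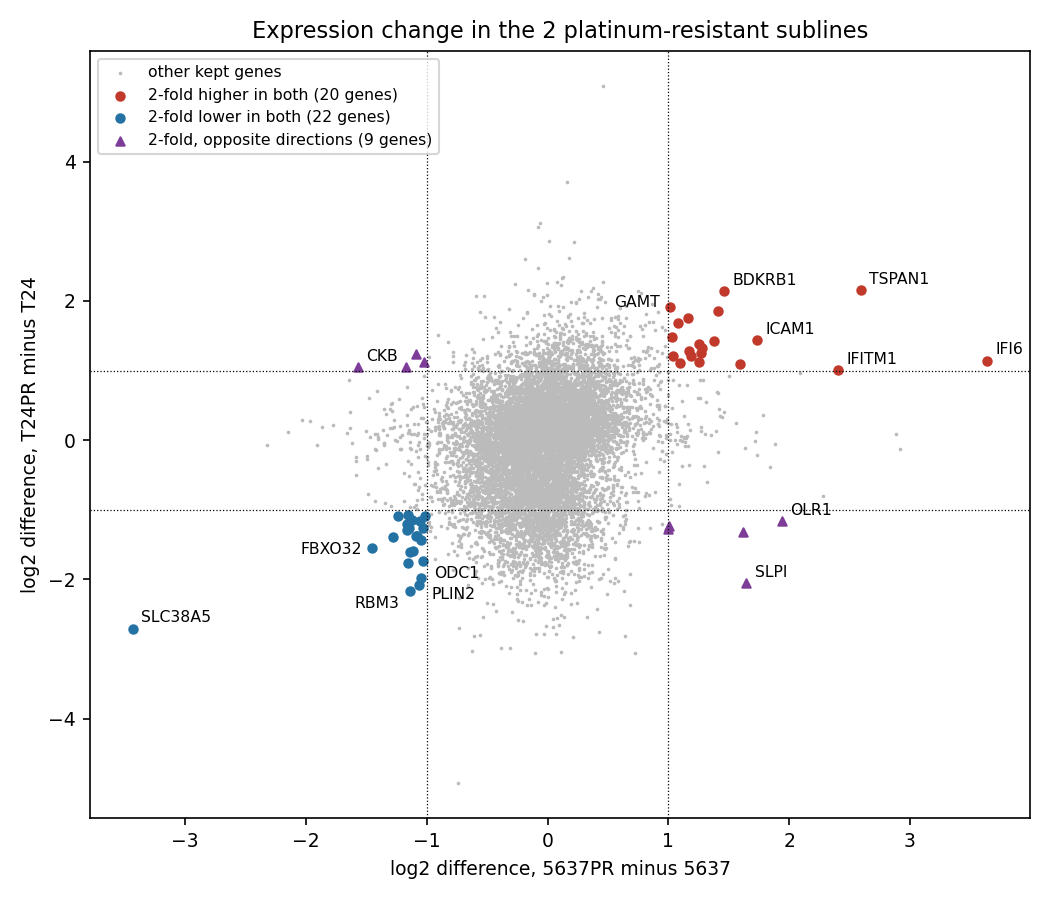
Log2 difference of 5637PR minus 5637 (x axis) against T24PR minus T24 (y axis) for the 10956 genes compared, 1 point per gene, with dotted lines at 2-fold. The coloured points are the 20 genes 2-fold higher in both, the 22 genes 2-fold lower in both, with SLC38A5 farthest out, and the 9 genes that differed in opposite directions.

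Genes of the EMT were examined because the series names it. The junction gene CDH1, which encodes E-cadherin, was at a log2 value of 8.30 in 5637 and 8.48 in 5637PR, and at 5.47 in T24, with a log2 difference of -0.47 in T24PR. CDH2, for N-cadherin, was at 7.98 and 8.02 in the 5637 pair and at 4.50 and 4.74 in the T24 pair, and VIM, for vimentin, was at 10.58 and 10.14 and at 10.85 and 10.83. The transcription factor genes SNAI1 and ZEB1 were at 5.19 and 5.02 and at 4.84 and 4.96 in the 5637 pair, and at 6.09 and 5.60 and at 6.36 and 6.04 in the T24 pair. The values of CDH1 and CDH2 in the T24 pair and of SNAI1 and ZEB1 in the 5637 pair were under the filter threshold. These genes had little room to be lower there, so the lack of a large decrease in those pairs says little. A large rise was not barred in this way, as IGSF10 was at 4.45 in T24 and 8.17 in T24PR. CDH2 in the T24 pair and SNAI1 and ZEB1 in the 5637 pair were not 2-fold higher, though a small rise under background could be missed. SNAI2 (-2.21) and TCF4 (-1.03) were 2-fold lower in T24PR, and TCF3 of the same list was higher by 1.24 there and differed by -0.43 in 5637PR. Of the mesenchymal and matrix genes, FN1 (-1.77) and SPARC (-1.48) were lower in 5637PR, while MMP1 (1.41) and ITGA5 (1.15) were higher, and in T24PR LOXL2 (2.33) and the smooth muscle actin gene ACTA2 (2.06) were higher, while DAB2 (-1.53) and TGFBI (-1.43) were lower. Of the 39 genes of this list, 2 were 2-fold higher and 2 lower in 5637PR, and 3 were higher and 5 lower in T24PR. The median of the mesenchymal list over 39 genes was -0.23 in the 5637 pair (percentile 0.19) and 0.24 in the T24 pair (percentile 96.5), and the difference between the pairs was not tested. The epithelial list had medians of -0.05 and 0.12 over 35 genes, the first turning to 0.01 after quantile normalization, with MAL2 at -0.74 and -4.92 and the desmosome gene DSP at 0.76 and -1.46. In T24PR 3 of these genes were 2-fold lower and 2 were 2-fold higher, TJP3 (1.53) and CLDN7 (1.03), and in 5637PR 0 were past 2-fold. The EMT transcription factors had a median of -0.10 in the T24 pair, which turned to 0.17 with the filter on the mean. Camera gave an adjusted p of 0.732 for the epithelial list, 0.997 for the mesenchymal list and 0.473 for the EMT transcription factors. For the epithelial list the mean over both lines was -0.05 while the median was 0.01. For the mesenchymal list camera pointed up while the mean (-0.03), the median (-0.05) and fry pointed down.

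**Figure D3:**
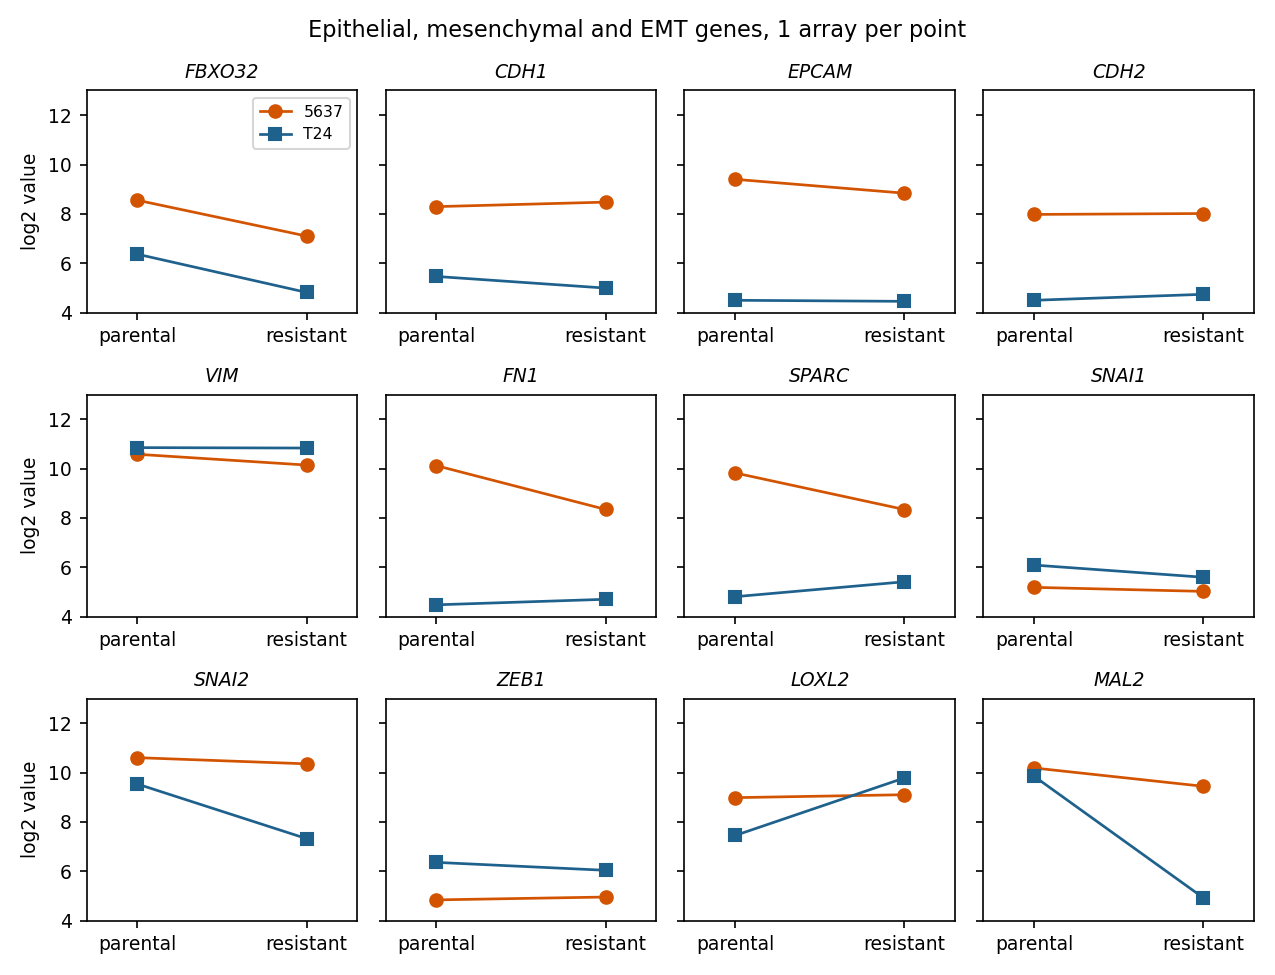
Deposited log2 values (y axis) of 12 genes on the parental and the resistant array (x axis) of 5637 (circles) and T24 (squares), 1 array per point. FBXO32 was lower on both resistant arrays (7.10 against 8.55 and 4.82 against 6.37). Its T24PR value was under the filter threshold, so the size of that difference is uncertain. CDH1, CDH2, VIM, SNAI1 and ZEB1 differed by less than 2-fold within each line. The values of CDH1 and CDH2 in the T24 pair and of SNAI1 and ZEB1 in the 5637 pair were also under that threshold. A decrease there could hardly be seen.

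Tested over both lines with camera, 5 of the 35 lists passed an adjusted p of 0.05. Each of these calls rests in part on the T24 array, which stood apart. At the preset correlation their p-values rest on the spread over genes, so they do not show that the 2 lines repeat each other. Interferon-stimulated genes were higher in the resistant sublines than other genes (adjusted p = 0.0153, adjusted p = 0.804 with an estimated correlation), with a mean log2 difference of 0.34. This call ended when the trend on gene span was removed (adjusted p = 0.0554). Genes of NF-kB and inflammatory cytokines were higher (adjusted p = 0.0370, adjusted p = 0.804 with an estimated correlation), among them ICAM1, TNFAIP2 (1.09 and 1.12) and the inhibitor gene NFKBIA (0.43 and 1.33). Of the 28 genes of this list, 5 were 2-fold higher in 5637PR and 4 in T24PR, but its medians of 0.03 (percentile 77.1) and 0.23 (percentile 95.8) lay within the central 95% of random lists, and the first turned to -0.01 without the filter and to -0.02 with the filter on the mean. That call ended without the filter (adjusted p = 0.136), with the span trend removed (adjusted p = 0.169) and without the block on cell line (adjusted p = 0.112). The ubiquitin ligase list was lower (adjusted p = 0.0153, adjusted p = 0.804 with an estimated correlation), with a mean of -0.42, and 16 of its 24 genes were lower in both lines. Its median was -0.73 in the T24 pair but -0.19 in the 5637 pair, at percentile 4.77 and so within the central 95% of random lists. FBXO32 was placed on this list from knowledge of the study, so its direction is not independent evidence, and without it the adjusted p was 0.0328. Proliferation genes (adjusted p = 0.0266, adjusted p = 0.804 with an estimated correlation) were lower, among them TYMS (-0.83 and -0.74) and CDC6 (-0.87 and -0.68). Unfolded protein and ATF4 genes (adjusted p = 0.0266, adjusted p = 0.804 with an estimated correlation) were lower, among them HERPUD1, HSPA5 (-0.49 and -0.83), CHAC1 (-0.77 and -0.85) and DDIT3 (-0.50 and -1.32), and the call ended without the block on cell line (adjusted p = 0.0511). Of the 39 genes of the unfolded protein list, 20 were lower in both lines and 6 higher in both, among the latter DDIT4 (0.81 and 0.27). The p with an estimated correlation rests on 1 degree of freedom and was not under 0.05 for any list before adjustment. It therefore says little about correlation between genes. The estimated correlation was -0.04 for interferon-stimulated, -0.02 for proliferation and -0.01 for unfolded protein genes, 0.05 for NF-kB genes and 0.02 for the ubiquitin ligase list. With 1 residual degree of freedom this estimate depends only on how many genes of a list deviate one way between the lines. It cannot be used to judge the preset of 0.01, so whether the preset is too low for these calls stays open. Over all alternatives the adjusted p ranged from 0.00279 to 0.804 for interferon-stimulated genes, from 0.0336 to 0.804 for NF-kB genes and from 0.00135 to 0.804 for the unfolded protein list. With fry, 0 lists passed an adjusted p of 0.05 (the smallest was 0.605) and 1 list had an unadjusted p under 0.05. That was the sterol synthesis list (fry unadjusted p = 0.0377), which is not among the 5 lists called by camera. Fry also rests on 1 residual degree of freedom here and could hardly call any list after adjustment, so its lack of calls says little. Adjusted over the list alone, limma called 1 gene, FBXO32 (adjusted p = 0.0427), and 0 genes in each of the other 34 lists, against 0 genes over all genes tested. Because FBXO32 was placed on its list from knowledge of the study, and nothing was corrected over the 35 lists, this call is not independent evidence for FBXO32.

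Genes of platinum handling were read because the sublines were resistant to platinum. The copper transporter gene SLC31A1, whose protein is also known to carry platinum into cells, differed by -0.25 in 5637PR and -0.66 in T24PR. The copper-exporting ATPase genes ATP7A (0.04 and -0.25) and ATP7B (0.19 and -0.21) differed little, and their sign in the T24 pair turned with the span trend removed (0.03 and 0.11). The efflux pump gene ABCC2 was near the lowest array values in 5637 (4.99) and 5637PR (5.05) and differed by -1.08 in T24PR. ERCC1 of nucleotide excision repair differed by -0.02 and 0.27, and the angiotensin receptor gene AGTR1 was below the filter on all 4 arrays. The platinum transport list had medians of 0.05 and 0.08 over 19 genes (camera adjusted p = 0.590), with the efflux pump gene ABCG2 at -2.09 in T24PR, LRRC8E at 0.99 in 5637PR and the copper chaperone gene ATOX1 at -0.56 and 1.15. Metallothioneins had medians of 0.08 and -0.08 over 9 genes (adjusted p = 0.898), with MT1E at -1.41 and MT1F at 1.00 in 5637PR. The NRF2 and glutathione list had medians of 0.02 and 0.02 over 40 genes (adjusted p = 0.590), with GPX2 higher by 1.46 in 5637PR and GCLM at -1.84 and TXNRD1 at -1.29 in T24PR. Nucleotide excision repair (medians -0.16 and 0.00 over 22 genes, adjusted p = 0.590, ERCC4 at -1.65 and DDB2 at 1.36 in T24PR) and mismatch repair (medians -0.25 and -0.43 over 8 genes, adjusted p = 0.204, MSH3 at -0.99 in T24PR) were not called. Crosslink and homologous recombination repair had an adjusted p of 0.116, with a median of -0.06 in the 5637 pair, and passed without the filter (adjusted p = 0.00450, range over all alternatives 0.00450 to 0.804).

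The p53 target list had medians of 0.04 and 0.28 over 26 genes (camera adjusted p = 0.670), with CDKN1A higher by 0.65 and 1.36, GDF15 by 0.30 and 1.77, and MDM2 at -0.17 and -1.76. Apoptosis regulators had medians of 0.10 and 0.15 over 27 genes (adjusted p = 0.473), with BAX at 0.09 and 1.32 and BAK1 at 0.65 and 0.64. In the cholesterol and sterol synthesis list 6 of 27 genes were 2-fold lower in T24PR and 0 in 5637PR, among them MSMO1 (-2.28) and SQLE (-1.96), while the list medians were -0.15 and -0.01 (adjusted p = 0.308). The last of these turned to 0.09 after quantile normalization. Luminal urothelial genes had medians of -0.21 and 0.04 over 14 genes (adjusted p = 0.473), with VGLL1 at -1.97 in 5637PR, PPARG at -1.03 and 0.52 and BAMBI at -0.32 and -1.22. The basal and squamous list had a median of 0.07 in the T24 pair (adjusted p = 0.354), with KRT13 at -1.42. In the TGF-beta list (medians -0.01 and 0.07 over 31 genes, adjusted p = 0.732) BMP4 differed by -1.09 and 1.24, and in the WNT list (medians 0.03 and 0.02 over 30 genes, adjusted p = 0.732) DKK1 was at -2.54 and FZD6 at -2.36 in T24PR. YAP targets (median -0.01 in the T24 pair, adjusted p = 0.491), stem cell markers (-0.09, adjusted p = 0.482) and angiotensin and angiogenesis genes (0.07, adjusted p = 0.491) were not called over both lines. Neither were the hypoxia and glycolysis list (medians 0.04 and 0.08 over 37 genes, adjusted p = 0.269, ANGPTL4 at 0.56 and 1.76) and the receptor tyrosine kinase list (-0.07 and 0.06 over 29 genes, adjusted p = 0.732, MET at -1.34 in T24PR). The ERK feedback list (median -0.20 in the 5637 pair, adjusted p = 0.370), antigen presentation (0.11, adjusted p = 0.0546), cancer testis antigens (-0.02, adjusted p = 0.164) and oxidative phosphorylation (-0.10, adjusted p = 0.0826) were not called either. Without the filter antigen presentation (adjusted p = 0.0295, range over all alternatives 0.0295 to 0.804) and oxidative phosphorylation passed (adjusted p = 0.00450, range 0.00450 to 0.804), the latter also with the span trend removed (adjusted p = 0.0351). Ribosomal protein genes had medians of -0.14 and 0.15 over 29 genes (adjusted p = 0.943), and reference housekeeping genes -0.08 and -0.17 over 22 genes (adjusted p = 0.204), which passed without the filter (adjusted p = 0.0451, range over all alternatives 0.0451 to 0.804). For the ribosomal and receptor tyrosine kinase lists camera pointed up while the mean and median over both lines were negative, and for the metallothionein and NRF2 lists the mean and the median differed in sign. Markers of other cell types were mostly below the filter: 4 of 19 leukocyte genes (medians -0.04 and 0.31, adjusted p = 0.670), 5 of 14 endothelial genes (0.27 and 0.01, adjusted p = 0.456) and 7 of 15 fibroblast genes (-0.02 and 0.14, adjusted p = 0.732) were kept.

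The parental lines were set against each other as context. GSTP1, a glutathione transferase gene, was at a log2 value of 12.42 in 5637 against 5.08 in T24, the basal keratin gene KRT5 at 11.97 against 4.70, the transglutaminase gene TGM2 at 12.43 against 5.29, KRT19 at 11.84 against 5.06 and WNT7A at 11.56 against 5.05. T24 was higher in CPS1, which encodes the carbamoyl phosphate synthetase of the urea cycle, with 11.40 against 4.57 in 5637, in HPD with 10.44 against 4.50, in DNAJC15 with 9.62 against 4.39, in LIFR with 9.75 against 4.60 and in OLR1 with 10.97 against 5.86. Apart from that of OLR1, the lower values of these genes were under the filter threshold, so their order by size is uncertain. At 2-fold or more, 1259 genes were higher in 5637 and 2143 in T24, and between the resistant sublines 864 were higher in 5637PR and 1151 in T24PR. The 2 sets of line differences had a Pearson correlation of 0.735 across genes. The epithelial list was higher in the 5637 arrays, with medians of 1.54 between the parental lines and 1.25 between the sublines, and the basal list likewise with 1.44 and 1.24. The mesenchymal list went from 0.69 between the parental lines to 0.03 between the sublines, and interferon-stimulated genes from -1.30 to -0.23, differences that were not tested. Within the pairs the interferon-stimulated genes had similar medians (0.28 in 5637PR and 0.32 in T24PR). The shift of that list's median between the lines therefore does not show a larger rise of the list in either subline.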

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

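No test was run on the results of this part, and only the removal of the span trend was chosen after seeing the data. Each of 9 genes was past 2-fold in one direction in 5637PR and in the other direction in T24PR, and the difference between the lines was not tested because each line has 1 array per side. The protease inhibitor gene SLPI was higher in 5637PR and lower in T24PR, and its T24 difference minus its 5637 difference was -3.70 on the log2 scale. The same value was -3.11 for the oxidized lipoprotein receptor gene OLR1, -2.94 for the guanine deaminase gene GDA, -2.28 for the metallothionein gene MT1F and -2.25 for the heat shock protein gene HSPA4L. In the other direction, lower in 5637PR and higher in T24PR, it was 2.62 for the creatine kinase gene CKB, 2.33 for the growth factor gene BMP4, 2.23 for the sialyltransferase gene ST6GAL1 and 2.15 for EPB41L2. With the span trend removed, 5 genes were past 2-fold in opposite directions.

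Probe sets with no gene symbol or with several were not part of any comparison. Of the 2494 such probe sets that reached the filter threshold, 6 were at least 2-fold higher in both sublines and 1 was at least 2-fold lower in both, and another 3 were past 2-fold in opposite directions.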

How the results depend on the processing

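The alternatives were planned, except the removal of the span trend, which was chosen after seeing the data. No correlation, list or named gene changed direction past its threshold under any of them. The balance of the 2-fold differences in 5637PR did turn, from 40.1% toward higher values as deposited to 56.6% after cyclic loess. With limma 0 genes passed an adjusted p of 0.05 under any setting, with a smallest adjusted p between 0.206 and 1. The block on cell line, the pairing that the labels give, mattered: with no replicate block 36 genes were higher and 32 lower at an unadjusted p under 0.05, against 236 and 377, and 1 list was higher by camera against 2. Without the filter on low values 403 of 18377 genes were higher at an unadjusted p under 0.05, against 236 of 10956. With the same 20 higher and 22 lower genes but more genes in all, the shared 2-fold genes exceeded independent lists by 6.28 times for higher and 2.22 times for lower genes (3.75 and 1.35 in the main setting), and 6 lists were lower by camera against 3. After cyclic loess 14 genes were 2-fold lower in both lines against 22. With the span trend removed 5 genes were opposite against 9, and 0 lists were higher by camera. With an estimated correlation 0 lists were higher and 0 lower, in a setting with 1 degree of freedom that could hardly call any list. At 1.5-fold in place of 2-fold, 163 genes were higher in both lines, 238 lower in both and 115 opposite, and the excess of shared higher genes was 2.33 times. Leaving out a line leaves 1 pair and no test: the number of genes with a mean difference of 2-fold or more, 121 higher and 218 lower, ranged from 91 to 642 higher and from 136 to 1318 lower, with the larger counts from the T24 pair and the smaller from the 5637 pair. The cause of these shifts was not tested, apart from the fewer arrays and the changed thresholds themselves.

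In all, 136 counts and correlations stayed within 1.5 times and the 19 given here moved. Of the camera results of single lists 264 stayed on their side of the threshold, 5 came to pass it and 10 no longer did. Of the values of named genes, 3410 moved by less than the spread and 18 by more. The sign differed under at least 1 alternative for 20 of 70 list medians, the largest of them 0.10 in size, and for 52 of 580 values of named genes, the largest of them 0.28 in size. The shift of all genes was at most 0.11 (T24 pair with the span trend removed, 0.05 as deposited). The arrays have a lowest value near 4.13, and its effect on the differences of dim genes was not tested.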

Other observations

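Apart from coding genes, the arrays measured 17 spliceosomal snRNA genes, 93 snoRNA genes and 11 scaRNA genes above the filter, and this comparison by RNA class was chosen after seeing the data. The median log2 difference was 0.33 in 5637PR and 0.88 in T24PR for snRNA genes, 0.17 and 0.31 for snoRNA genes and 0.19 and 0.92 for scaRNA genes, against -0.03 and 0.04 for 10502 protein-coding genes. In T24PR 8 snRNA genes, 25 snoRNA genes and 5 scaRNA genes were 2-fold higher, and 0, 9 and 0 were 2-fold lower. Short genes also differed from long ones: the 1051 coding genes with a span of up to 4600 bases had medians of 0.10 and 0.25. Set against these genes, the 121 small RNA genes were higher by 0.09 (bootstrap interval 0.01 to 0.19) in 5637PR and by 0.26 (0.06 to 0.43) in T24PR, intervals that cover the spread over genes and not over cultures. The coding genes were not matched to the small RNA genes on span, so this comparison cannot separate RNA class from gene span. Across all genes span correlated with the log2 difference at a Spearman value of -0.14 in the 5637 pair and -0.25 in the T24 pair, and with 5637 minus T24 at -0.24.

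Of the tests that follow, those of a mixed culture and of neighbouring genes were chosen after the results had been seen, and those that remove the span trend after that trend had been seen. In 813 genes the T24 array lay at least 1 on the log2 scale from the mean of the other 3 arrays while those lay within 0.5 of each other, 712 of them higher in T24. The same count was 161 for T24PR, 31 for 5637 and 23 for 5637PR. An intensity-dependent trend and a span trend are argued against as the whole cause, since T24 still had 5.583 times the genes of the next array after cyclic loess (5.05 as deposited), and after removing the span trend it had 3.982 times. RNA from 5637 cells in T24PR is also argued against, as 20 genes strong in 5637PR and at the floor in T24 stood in T24PR at a median of 0.3507% of their 5637PR level. What stays open is a difference of the T24 cells or a fault of the single T24 array or its RNA, because T24 has no second array, and GC content was not analysed here.

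Neighbouring genes differed together in both pairs of arrays: along the gene order of GRCh38.p14, windows of 21 genes passed bounds from 1000 shuffled orders in 12 lower and 4 higher blocks of the 5637 pair and in 15 lower and 14 higher blocks of the T24 pair. For the 12 lower blocks of 5637PR, paralogs sharing probes are argued against, since the largest share of genes with one symbol stem in any block was 0.0952. A regional trend of the measurement common to both pairs, with at least 0.5 of its T24 size in the 5637 pair, is argued against for the 15 lower blocks of T24PR, since in 15 of them the 5637-pair interval lay above 0.5 of the T24 median (medians from -1.10 to -0.54 in the T24 pair and from -0.09 to 0.07 in the 5637 pair). These blocks were picked for low medians in the T24 pair. A smaller common trend, or a regional trend of the T24 or T24PR array alone, is not covered by this and stays open. For the 12 lower blocks of 5637PR a regional trend common to both pairs cannot be told apart from a change in that subline alone, because the T24-pair interval lay above 0.5 of the 5637 median in 3 blocks (such as BHLHE40 to CHCHD4, median -0.52 in the 5637 pair and 0.15 relative to all genes in the T24 pair), and lay below 0 and reached that level in another 3 (such as STK17B to CREB1, -0.44 and -0.77). Of the 4 higher blocks of the 5637 pair, the relative T24-pair interval lay above 0 in 1 (median 0.34) and below 0 in 1 of 131 genes (median 0.38 in the 5637 pair and -0.38, interval -0.55 to -0.18, in the T24 pair), and no biological explanation of any block was tested.

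More genes were higher in both sublines than independent lists give, 20 against 5.33. After the trend on gene span was removed from each pair the excess was 2.628 times, so that trend is argued against as the whole cause. The acquired resistance and a difference in handling between parental and resistant cultures both stay open and untested.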
